A study of Mus musculus with 309 samples.

How the data were processed

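Bulk RNA sequencing of poly(A) RNA was analysed from 309 mouse mammary tumours of 24 tumour models. Per the labels, RNA came from frozen tumours after homogenisation, and libraries were made with a TruSeq mRNA kit. The strandedness of the libraries is not stated in the sources used here. Tumours were grouped by the model and treatment in their titles, which gave 100 groups, mostly of 3 tumours. For 3 tumours titled KPB25L-UV with carboplatin plus paclitaxel, the library names begin with KPB25L instead; they were kept in the group of their title. The tumours carry running library numbers, and the labels do not say whether these follow the date of collection or sequencing.

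Per the submitters' processing notes, reads were processed with STAR, SAMtools, Picard and Salmon on the mm10 build; versions and settings are not given in the sources used here. The deposited count table holds Salmon's estimated counts, unscaled between libraries, for 55291 gene symbols, and 8.35% of its values were not whole numbers. The authors' second table holds a normalized signal. It was checked against the first: each value was the estimated count divided by the 75th percentile of that library's values above 0 and multiplied by 1000, with a largest relative deviation of 5.2e-15. Every column was joined to a tumour by its library name. Gene positions came from GENCODE M21 on the same build, in which 53292 of the symbols were found. Genes with near-identical copies, such as the haemoglobin genes, granzymes d to g, the lysozyme pair and mitochondrial genes, share reads, so values of single members are uncertain.

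Estimated counts were rounded and genes with low counts removed with filterByExpr of edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Libraries were scaled by trimmed means of M values (TMM). Expression is given as CPM, counts scaled to a common library total, and on the log2 scale with a prior count of 2. Each treatment was compared with untreated tumours in the models that held both arms, with edgeR's quasi-likelihood test and the model as a factor. Trametinib was also compared with erlotinib, and anti-PD1 plus anti-CTLA4 with carboplatin plus paclitaxel. Further tests asked whether responses differed between models (interaction F-test), which genes changed within single models, and which differed between untreated models and between T11-APOBEC or KPB25L-UV and their namesakes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The p-values of gene tests over tumours measure the spread between tumours. Pooled over models, these tests treat tumours of the same model as independent, so they do not give the spread of a response over models. Tests whose points are models, such as those of survival and of differences per model, measure the spread between models. Library totals ranged from 12.1 M to 226 M counts (M, mega). Counting error is therefore small beside the spread between tumours for all but the rarest transcripts.

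The groups, tests, thresholds, 32 gene lists and the rule for named genes were fixed before the data were examined. The lists were ERK pathway output; EGFR family and ligands; receptor tyrosine kinases outside the EGFR family; cell proliferation; p53 target genes; type I interferon response; interferon gamma and MHC class I; MHC class II; cytotoxic T and NK cells; regulatory T cells and checkpoint receptors; B cells and plasma cells; macrophages; neutrophils; dendritic cells; epithelial and tight junction; mesenchymal transcription and adhesion; luminal hormone response; alveolar and milk; basal and myoepithelial; fibroblasts and extracellular matrix; endothelial cells; adipocytes; skeletal muscle; skin keratinocytes; erythrocytes; hypoxia and glycolysis; immediate early and handling stress; unfolded protein and amino acid stress; cholesterol synthesis; tubulins and drug efflux; senescence secretory; and Wnt and stem signalling. Kdr, Sesn2, Btg2, Bst2, Il1b, Cxcl1 and Cxcl2 each stood in a pair of lists.

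Lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data; a list was called at an adjusted p under 0.05 over the lists. Members were counted as higher or lower over all tested genes and also adjusted over the list alone. Named genes were, in each comparison, the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 2 that went the same way in at least 75% of the models. Predicted genes and pseudogenes were left out. Named too were the 2 members with the smallest p in each of the 6 called lists with the smallest p, and always Egfr, Dusp6, Spry4, Pdcd1, Ctla4, Cd274, Cd8a, Gzmb, Mki67 and Cdkn1a. For untreated models 13 further genes were fixed. A gene of these and a gene named by the rule are not reported here.

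Median survival in days, which the labels give for each model and treatment, was compared by an exact two-sided sign-flip permutation test of the log2 ratio over models. List levels and changes were set against that ratio by Pearson's r and Spearman's rho with permutation p-values (Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3; figures with matplotlib 3.10.9). The share of variance by model, treatment and their interaction was averaged over genes without a test.

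Alternatives, whose effect the closing section gives, were DESeq2 1.42.0, other size factors, no low-count filter, limma on the authors' normalized table with a pseudocount of 1, no model factor, 1 difference per model as the unit, untreated tumours marked for the same set only, and leaving out single replicates or models. Models were also split by whether the mean library numbers of the compared arms lay within 100 of each other, called near here, or further apart, called far. Library total as a covariate, skeletal muscle and adipocyte levels as covariates, leaving out the tumours above the upper quartile of the skeletal muscle level, and the near and far split of anti-PD1 plus anti-CTLA4 against carboplatin plus paclitaxel were chosen after seeing the data. Further alternatives fitted each model or each derivative pair alone, measured survival in days, or left out the derivative models. The fits were also run on simulated counts with known changes and an assumed spread, in the last case changed in 1 model only and in the last pair of cases only among genes with means above 20 counts. At simulated folds of 0.25, 0.5, 2 and 4, the comparison of trametinib with untreated tumours recovered 100% of the changed genes left by the low-count filter. These numbered 45 at the fold of 0.25 and 50 at each of the others. The comparison of T11-APOBEC with T11 recovered 90%, 30%, 10% and 88%, and the interaction test for erlotinib 24%, 0%, 2% and 44%. False calls numbered 12, 7 and 1 in that order. The tumour models E0771 and KPB25L-APOBEC had 1 untreated tumour each; E0771 entered the comparisons with the model as a factor and those with survival, and KPB25L-APOBEC entered none.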

Results

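Poly(A) RNA was sequenced from 309 mammary tumours of 24 mouse models, which the title of the series places under triple-negative breast cancer. It names the purpose as profiling genetically diverse models under immunotherapy, chemotherapy, erlotinib or trametinib. Untreated tumours numbered 64 (18 models), and 65 tumours (22 models) had been given trametinib, an inhibitor of the kinase MEK. Another 66 (22 models) had been given erlotinib, an inhibitor of the receptor EGFR, and 66 (22 models) carboplatin plus paclitaxel, a DNA-damaging drug with one that binds microtubules. The last 48 (16 models) had been given antibodies against PD1 and CTLA4, receptors that restrain T cells. Most of the 100 combinations of model and treatment held 3 tumours. The labels give no dose and no time of collection. Library totals had a median of 78.6 M estimated counts (range 12.1 M to 226 M; M, mega), and a median of 22958 genes had at least 1 count. Median totals were 76.9 M in untreated tumours, 39.3 M with trametinib, 34.3 M with erlotinib, 103 M with carboplatin plus paclitaxel and 113 M with anti-PD1 plus anti-CTLA4. Mitochondrial genes took a median of 2.47% of counts in untreated tumours, 3.30% with trametinib, 3.19% with erlotinib, less than untreated with chemotherapy and 1.79% with the antibodies. Depth differed between ranges of the running library number, with medians of 53.9 M for the 6 tumours of the lowest numbers, 27.3 M for the next 105, 83.7 M for another 133 and 126 M for the 65 of the highest. Treatments were spread unevenly over these numbers: 39 trametinib, 39 erlotinib, 9 chemotherapy and 18 untreated tumours, and none given antibodies, were among the 105. Models are therefore called near below where the mean library numbers of the compared arms lay within 100 of each other, and far where they did not. By these means KPB1-B, T11 and p53RB-626 are far with trametinib and erlotinib, though some of their untreated tumours lay beside the treated ones. The same holds for KPB1-B and p53RB-626 with chemotherapy. Far models thus hold some untreated tumours close to treated ones, which limits the split as a check of batches.

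The first comparison asked how the untreated models differ, over 62 tumours of the 16 models with at least 3. They fell into 9 models with high Epcam, an adhesion protein of epithelial cells, and 7 models almost without it. Erbb2, the receptor kinase that drives MMTV-Neu tumours, was far higher in MMTV-Neu than in any other model. Genes of milk were high only in the MMTV-Neu and MMTV-PyMT models, and genes of cytotoxic lymphocytes, macrophages and interferon responses were lowest in KPB1-A and KPB1-B. Of 22779 tested genes, 22520 differed between models. Epcam (chromosome 17, mm10) had mean CPM of 279 to 1854 in one set and 0.325 to 3.12 in T12, T11-APOBEC, T11, K14-TRT, p53RB-626, p53RB-624 and p53RB-426 (adjusted p = 5.47e-37 over models). Vim, an intermediate filament of mesenchymal cells, went the other way, at 2438 to 4484 in these 7 models and 137 to 943 in the others (adjusted p = 1.38e-25). Erbb2 reached 12524 ± 2268 CPM (SD, n = 3) in MMTV-Neu and 6.55 to 171 elsewhere (adjusted p = 1.11e-52). Trp53, which encodes the tumour suppressor p53, ranged from 12.5 ± 1.94 CPM (SD, n = 3) in KPB1-A to 188 ± 10.1 (SD, n = 3) in T12 (adjusted p = 7.92e-35). Brca1, a gene of DNA repair, ranged from 12.0 in KPB25L to 82.2 in C3-TAG. Rb1, which holds back the cell cycle, ranged from 10.9 in p53RB-426 to 63.2 in C3-TAG. Krt14, a keratin of basal cells, was highest in C3-TAG (570 ± 283, SD, n = 4). Egfr ranged from 8.68 in 2153 to 89.3 in K14-TRT, and Esr1, the oestrogen receptor, from 1.75 in KPB1-B to 40.8 in p53RB-426. The alveolar and milk list had a mean log2 CPM of 7.40 in MMTV-Neu and 6.19 in MMTV-PyMT, and -4.50 to 0.17 in the other models. The cytotoxic T and NK cell list ranged from -3.42 in KPB1-A and -2.78 in KPB1-B to 1.80 in p53RB-626. Type I interferon response levels were 1.49 in KPB1-B and 1.86 in KPB1-A, against 3.17 to 5.15 elsewhere. Cd8a, a receptor chain of cytotoxic T cells, had mean CPM of 0.0848 to 6.52, Cd79a of B cells 0.0686 to 1.44, and S100a8 of neutrophils 0.370 to 19.2. Model and library number were confounded for most models, so differences between models may include those between batches, which was not tested.

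Next was how much expression depended on treatment at all, and whether treated animals lived longer. Tumour model accounted for 59.8% of the variance of log2 CPM, treatment for 2.90%, the interaction of both for 16.3% and tumours within groups for 21.0%, averaged over 25181 genes (221 tumours, 15 models). These shares are of sums of squares, uncorrected for the number of terms fitted, so that noise enters the interaction share. They do not separate model or treatment from library number. Median survival in the labels was longer with trametinib in 15 of 16 models and equal in 1, with a median ratio of 1.48 (exact two-sided sign-flip permutation p = 6.10e-05, adjusted p = 0.000244 over 4 treatments). Carboplatin plus paclitaxel lengthened it in 13 of 16 models, with a median ratio of 1.35 (exact permutation p = 0.000244, adjusted p = 0.000488). With erlotinib it was longer in 9 of 16 models and shorter in 2, with a median ratio of 1.13 (exact permutation p = 0.00781, adjusted p = 0.0104). Anti-PD1 plus anti-CTLA4 gave a median ratio of 1.09, longer in 7 of 12 models and shorter in 3 (exact permutation p = 0.0488, adjusted p = 0.0488), and measured in days the exact permutation p was 0.0605. The largest ratios were 4.64 for KPB1-B and 4.25 for KPB1-A with carboplatin plus paclitaxel, 4.3 for 2153 with trametinib, 2.8 for E0771 with the antibodies and 1.71 for KPB1-B with erlotinib.

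Trametinib was compared with no treatment to ask how tumours respond to MEK inhibition. Genes switched on by the kinase ERK, which MEK activates, fell, among them Dusp6 and Spry4, feedback inhibitors of that pathway. Genes of cell division, cholesterol synthesis and blood vessels also fell. Genes of the extracellular matrix and of the interferon response rose. Of 18014 genes, 3433 were higher and 3782 lower (48 treated and 54 untreated tumours, 16 models). Dusp6 (chromosome 10, 99263231 to 99267489) fell from 243 ± 152 to 98.6 ± 51.0 CPM (SD), with a log2 fold change of -1.27 ± 0.0832 (SE; adjusted p = 1.92e-22) and lower means in 16 of 16 models. Spry4 changed by -0.83 ± 0.0843 and the ERK-induced transcription factors Egr3 by -1.89 ± 0.153 and Egr1 by -1.64 ± 0.148. In the ERK pathway output list 17 of 22 members fell and 1 rose, the same number adjusted over the list alone (adjusted p = 4.9e-12, and adjusted p = 0.00954 with an estimated correlation). It was the only list of 17 called that kept its call with an estimated correlation. All 35 members of the cell proliferation list fell (35 adjusted over the list alone; adjusted p = 2.97e-30, and adjusted p = 0.116 with an estimated correlation). Mki67, a marker of dividing cells, fell by 0.82 ± 0.101 on the log2 scale (adjusted p = 2.81e-10). Within near models the ERK list change was -0.48 ± 0.082 (SE, 8 models) and in far models -0.60 ± 0.065 (SE, 8 models). Proliferation changed by -0.28 ± 0.088 in near models and by more in far ones. Cholesterol synthesis fell in 17 of 19 members (18 adjusted over the list alone; adjusted p = 1.65e-13, and adjusted p = 0.116 with an estimated correlation). In near models the median change of this list was only -0.110 (SE 0.134, below 0 in 7 of 8 models). Endothelial genes fell in 15 of 19 members (adjusted p = 3.06e-10, and adjusted p = 0.187 with an estimated correlation). Among them Mmrn2, a matrix protein of vessels, was lower in 16 of 16 models (-0.89 ± 0.0894). In the list of fibroblasts and extracellular matrix 19 of 23 members rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 7.58e-13, and adjusted p = 0.148 with an estimated correlation). Sfrp2, a secreted Wnt modulator (chromosome 3, 83766321 to 83774316), rose from 26.8 ± 31.3 to 112 ± 135 CPM (SD; log2 fold change 1.97 ± 0.172, adjusted p = 4.86e-16), and Postn, a matrix protein of fibroblasts, from 610 ± 422 to 1371 ± 946. The largest rises also held Omd and Ogn, matrix proteoglycans, and Saa1, an acute-phase protein (2.38 ± 0.361). Type I interferon genes rose in 21 of 28 members (adjusted p = 3.31e-09, and adjusted p = 0.369 with an estimated correlation), and those of interferon gamma and MHC class I in 12 of 24 (14 adjusted over the list alone; adjusted p = 1.45e-05, and adjusted p = 0.41 with an estimated correlation). Cytotoxic T and NK genes had list changes of -0.01 ± 0.38 in near models, with E0771 (1 untreated tumour) at -2.06 and the others at -0.73 to 1.03, and of 0.73 ± 0.22 in far models. Cd274, which encodes the PD1 ligand, rose by 0.69 ± 0.123 over all models, but stood at 0.20 in near models, where it passed no test, against 1.14 in far ones. Egfr itself rose by 0.29 ± 0.081 (adjusted p = 0.00232; no longer past the test in near models), Ctla4 fell by 0.62 ± 0.199, and Cd8a, Pdcd1, Gzmb and the cell cycle inhibitor Cdkn1a passed no test. Near models alone gave fewer genes than far models, which gave 5447, and with 1 difference per model as the unit 1559 were called. Without a term for the model there were 1357, and 4370 without the tumours highest in muscle.

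Erlotinib was compared with no treatment to ask how tumours respond to EGFR inhibition. Genes of cholesterol synthesis fell in nearly every model, led by Cyp51 and Fdps, enzymes of that pathway. Genes of cell division fell, and a few macrophage genes rose. Few targets of ERK passed the test. Of 17954 genes, 849 were higher and 942 lower (48 treated and 54 untreated tumours, 16 models). Cyp51 (chromosome 5, 4081145 to 4104746) fell from 108 ± 84.6 to 76.5 ± 58.3 CPM (SD; log2 fold change -0.56 ± 0.0732 SE, adjusted p = 1.05e-07), and Fdps changed by -0.53 ± 0.0734, each lower in 16 of 16 models. The cholesterol list fell in 17 of 19 members (18 adjusted over the list alone; adjusted p = 1.07e-26, and adjusted p = 0.00556 with an estimated correlation), the only list of 13 called that kept its call. Its change was -0.14 ± 0.051 in near models (below 0 in 6 of 8) and -0.58 ± 0.097 in far models, and Cyp51 in near models stood at -0.32 and did not pass. Proliferation genes fell in 32 of 35 members (34 adjusted over the list alone; adjusted p = 1.61e-27, and adjusted p = 0.261 with an estimated correlation), but the near models had a list change of only -0.02 ± 0.046 against -0.76 ± 0.39 in far ones, where MMTV-Neu stood at -3.37 and its skeletal muscle list at 4.47. Mki67 fell by 0.47 ± 0.131 over all models and stood at 0.03 in near models. Dusp6 changed by -0.39 ± 0.0941 (adjusted p = 0.00483) and Etv4, an ERK-induced transcription factor, by -0.48 ± 0.146, and 2 of 22 ERK members fell (adjusted p = 0.00346, and adjusted p = 0.611 with an estimated correlation). Egfr had a log2 fold change of -0.21 ± 0.0856 that passed no test (adjusted p = 0.0968), as did Spry4, Cd274, Gzmb, Pdcd1, Cd8a, Ctla4 and Cdkn1a. Gpnmb, a glycoprotein of phagocytes, rose by 1.31 ± 0.251 and in 15 of 16 models, and Mmp12, a macrophage elastase, by 1.29 ± 0.26. The macrophage list rose in 3 of 19 members (6 adjusted over the list alone; adjusted p = 5.95e-06, and adjusted p = 0.611 with an estimated correlation), with changes of -0.10 ± 0.097 in near and 0.67 ± 0.37 in far models (2.84 in MMTV-Neu). The largest falls included the protease Klk10 at -1.32 ± 0.276 and the desmosomal Dsg3 at -1.25 ± 0.333. Epithelial genes fell in 2 of 23 members, among them Cdh1, which encodes E-cadherin (-0.51 ± 0.143), and mesenchymal genes rose in 2, Prrx1 and Zeb1, which encode transcription factors. These are small counts, where 9.98% of all tested genes were called. Only 190 genes were called over near models and 2358 over far ones, and none with 1 difference per model as the unit in limma (961 at unadjusted p under 0.05; lowest adjusted p 0.827), where DESeq2 over tumours called 1541. Leaving out 1 replicate of every group gave 252 to 864, leaving out the tumours highest in muscle 461, and no term for the model 172. Without 1 model the count ran from 1111 (MMTV-Neu left out) to 2037 (2153 left out). On the authors' normalized table with limma 306 were higher and 2462 lower.

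Trametinib and erlotinib were also compared directly in 22 models, whose arms all lay near in library number, to ask what MEK inhibition does beyond EGFR inhibition. ERK targets and vessel genes were lower with trametinib. Interferon genes, antigen presentation genes and extracellular matrix genes were higher. Of 16778 genes, 2231 were higher and 2214 lower with trametinib (65 against 66 tumours). Dusp6 was lower in 19 of 22 models (-0.70 ± 0.0752 SE, adjusted p = 8.55e-13), and 16 of 22 ERK members were lower and 1 higher (adjusted p = 9.88e-09, and adjusted p = 0.0825 with an estimated correlation). Areg, an EGFR ligand, was lower (-1.45 ± 0.175), while Egfr was higher (0.48 ± 0.0803). Type I interferon genes were higher in 26 of 28 members (adjusted p = 2.06e-19, and adjusted p = 0.155 with an estimated correlation). Ifit1, an antiviral protein (chromosome 19, 34640871 to 34650009), had 32.5 ± 46.2 CPM with trametinib and 17.1 ± 24.3 with erlotinib (SD; log2 fold change 0.94 ± 0.125, adjusted p = 2.97e-09), higher in 21 of 22 models. Interferon gamma and MHC class I genes were higher in 19 of 24 members (21 adjusted over the list alone; adjusted p = 4.72e-12, and adjusted p = 0.157 with an estimated correlation). Cytotoxic genes were higher in 11 of 22 (adjusted p = 5.94e-07, and adjusted p = 0.354 with an estimated correlation), and Cd8a differed by 0.76 ± 0.173. Endothelial genes were lower in 17 of 19 members (18 adjusted over the list alone; adjusted p = 4.12e-17, and adjusted p = 0.0781 with an estimated correlation), with Mmrn2 lower in 20 of 22 models. Collagen Col1a1 differed by 0.83 ± 0.154, and 20 of 23 matrix members were higher (adjusted p = 1.42e-13, and adjusted p = 0.157 with an estimated correlation). Macrophage genes were lower in 8 of 19 members and higher in 1 (adjusted p = 2.31e-06, and adjusted p = 0.354 with an estimated correlation). With 1 difference per model as the unit 394 genes were called, 239 without a term for the model, 2579 without the tumours highest in muscle and 1894 to 3112 without 1 replicate of every group. On the authors' normalized table with limma 3024 were higher and 1506 lower.

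Carboplatin plus paclitaxel was compared with no treatment to ask how tumours respond to chemotherapy. Genes listed as p53 targets rose, led by Cdkn1a, which stops the cell cycle after DNA damage. Whether p53 itself raised them was not tested. Genes of interferon responses and of cytotoxic lymphocytes rose in most models, and cholesterol synthesis fell. In the 5 near models (28 tumours) edgeR called 0 of 17241 genes (2015 at unadjusted p under 0.05), and in the 11 far models (74 tumours) 5634, so the sets also differ in size. Over all 16 models, 2852 of 18401 genes were higher and 2057 lower (48 treated and 54 untreated tumours), and DESeq2 called 5272. On the authors' normalized table with limma 5128 were higher and 736 lower. Cdkn1a (chromosome 17, 29090976 to 29100727) rose 2.75-fold, from 60.9 ± 36.1 to 170 ± 128 CPM (SD; log2 fold change 1.46 ± 0.127, adjusted p = 5.34e-15), and in 15 of 16 models. In near models its value was 0.77, which did not pass, and in far models 1.74. Ephx1, a detoxifying enzyme under p53, rose in 16 of 16 models by 1.08 ± 0.107 (0.98 in near models, which did not pass). The p53 list rose in 20 of 24 members (20 rises and 1 fall adjusted over the list alone; adjusted p = 1.1e-17, and adjusted p = 0.00887 with an estimated correlation), with changes of 0.15 ± 0.13 in near and 0.62 ± 0.13 in far models. Of the near models E0771, with 1 untreated tumour, was at -0.33 and the others at 0.12 to 0.44. The list also rose in p53RB-426, p53RB-624 and p53RB-626 (0.30, 0.44 and 0.30), whose names point to p53. Among the far models C3-TAG, MMTV-Neu and MMTV-PyMT stood at 1.44, 1.27 and 1.02, and the others at 0.26 to 0.58. Cholesterol synthesis fell in 17 of 19 members (19 adjusted over the list alone; adjusted p = 1.95e-22, and adjusted p = 0.00887 with an estimated correlation), with like changes in near and far models (-0.44 ± 0.12 and -0.44 ± 0.096). Idi1 and Hmgcs1, enzymes of that pathway, were lower in 16 of 16 models (-0.74 ± 0.0938 and -0.62 ± 0.0676). These were the only lists of 18 called that kept the call with an estimated correlation. All 28 type I interferon members rose (adjusted p = 1.35e-19, and adjusted p = 0.306 with an estimated correlation), by 0.30 ± 0.33 in near and 0.92 ± 0.16 in far models. Cytotoxic genes rose in 18 of 22 members (21 adjusted over the list alone; adjusted p = 3.21e-08, and adjusted p = 0.424 with an estimated correlation), by 1.02 ± 0.30 in far models and -0.00 ± 0.80 in near ones, where E0771 stood at -2.54 and the others at -0.67 to 2.32. Prf1, which perforates target cells, rose by 1.80 ± 0.337, Ccl5, a chemokine of T cells, by 1.38 ± 0.218, and Fcrl6, a receptor of cytotoxic lymphocytes, by 3.02 ± 0.325. Granzymes Gzmg, Gzmf and Gzmd had rises of 2.04 to 3.09, with reads that these copies share. Gzmb rose by 1.12 ± 0.307, Pdcd1 by 1.00 ± 0.228 and Cd274 by 0.91 ± 0.146. Ctla4 and Cd8a rose by 0.86 and 0.68, but stood at -0.47 and -0.10 in near models. Mki67 fell by 0.39 ± 0.0884, and 5 of 35 proliferation genes fell (adjusted p = 0.000383, and adjusted p = 0.658 with an estimated correlation). Macrophage, neutrophil and regulatory T cell lists rose as well, with 12, 6 and 8 members higher (adjusted p = 0.463, 0.424 and 0.424 with an estimated correlation). With 1 difference per model as the unit, limma called 0 genes (2914 at unadjusted p under 0.05; lowest adjusted p 0.1). Counts were 2225 against the untreated tumours that the labels mark for this treatment, 3071 with depth as a covariate, 782 without a term for the model and 2139 without the tumours highest in muscle.

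Anti-PD1 plus anti-CTLA4 was compared with no treatment in 12 models to ask how tumours respond to checkpoint blockade. Genes of skeletal muscle fell in all 12 models. Genes of glycolysis under hypoxia rose, and so did part of the genes of cytotoxic lymphocytes and of interferon gamma. Untreated and treated tumours were near in library number in 2 models only, MMTV-Neu and MMTV-PyMT. Of 18371 genes, 1353 were higher and 1142 lower (36 treated and 41 untreated tumours). Myh4, a myosin of fast muscle fibres (chromosome 11, 67238029 to 67260446), fell from 134 ± 207 to 15.0 ± 21.3 CPM (SD; log2 fold change -3.87 ± 0.653, adjusted p = 1.7e-05). All 16 members of the skeletal muscle list fell (16 adjusted over the list alone; adjusted p = 1.03e-30, and adjusted p = 0.03 with an estimated correlation), with list changes of -1.69 ± 0.87 in near and -2.78 ± 0.47 in far models, the smallest -0.72 in p53RB-626. It was the only list of 13 called that kept its call with an estimated correlation. Adipocyte genes fell in 8 of 13 members (9 adjusted over the list alone; adjusted p = 6.95e-05, and adjusted p = 0.618 with an estimated correlation). With muscle and adipocyte levels as covariates, which remove such changes by construction, Pvalb, Acta1 and Car3, genes of muscle and fat, changed sign. Hypoxia and glycolysis genes rose in 13 of 18 members (14 adjusted over the list alone; adjusted p = 4.78e-11, and adjusted p = 0.342 with an estimated correlation), of which 2 kept the call with muscle and adipocyte levels as covariates. Among them Pgk1, a glycolytic enzyme (chromosome X, 106187100 to 106203699), rose from 620 ± 219 to 882 ± 373 CPM (SD; log2 fold change 0.52 ± 0.0992, adjusted p = 0.00018), with 0.26 in near models, which did not pass. Cytotoxic genes rose in 7 of 22 members (8 adjusted over the list alone; adjusted p = 0.000229, and adjusted p = 0.618 with an estimated correlation), by 0.60 ± 0.66 in near and 0.39 ± 0.26 in far models. Prf1 rose by 1.14 ± 0.269, Gzmb by 0.66 ± 0.188 and Fasl, a ligand that kills target cells, by 0.61 ± 0.176. Cd274 rose by 0.71 ± 0.127 in 10 of 12 models, whereas Cd8a, Pdcd1 and Ctla4 passed no test (adjusted p = 0.149, 0.0723 and 0.0633). Interferon gamma and MHC class I genes rose in 8 of 25 members (14 adjusted over the list alone; adjusted p = 8.18e-05, and adjusted p = 0.618 with an estimated correlation). S100a9, a calcium-binding protein of neutrophils, rose by 1.25 ± 0.261, and Egfr fell by 0.27 ± 0.0764 but stood at 0.16 in near models. Dusp6, Spry4, Mki67 and Cdkn1a passed no test. The called genes numbered 150 over near models and many more over far ones, and 0 with 1 difference per model as the unit in limma (1686 at unadjusted p under 0.05; lowest adjusted p 0.107), where DESeq2 over tumours called 2469. They numbered 717 with depth as a covariate, 1367 against the untreated tumours marked for this treatment, 279 without a term for the model, 524 to 1006 without 1 replicate of every group, 3990 without MMTV-PyMT and 1199 without p53RB-426.

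A direct comparison of the antibodies with chemotherapy in 16 models asked which responses belong to either. Genes listed as p53 targets were lower with the antibodies. Cholesterol synthesis, haemoglobin, hypoxia and proliferation genes were higher, and muscle genes lower. Of 18705 genes, 1763 were higher and 2179 lower with the antibodies (48 against 48 tumours). Proliferation genes were higher in 13 of 35 members (15 adjusted over the list alone; adjusted p = 8.05e-08, and adjusted p = 0.486 with an estimated correlation). Cdkn1a was lower in 15 of 16 models (-1.19 ± 0.147, SE, log2 scale; adjusted p = 9.35e-09), and Ccng1, a cyclin under p53, was lower too (-0.81 ± 0.0892). The p53 list was lower in 21 of 24 members (22 adjusted over the list alone; adjusted p = 3.63e-19, and adjusted p = 0.0138 with an estimated correlation). Cholesterol genes were higher in 18 of 19 (adjusted p = 9.39e-18, and adjusted p = 0.0325 with an estimated correlation), and hypoxia genes in 15 of 18 (16 adjusted over the list alone; adjusted p = 1.93e-16, and adjusted p = 0.0408 with an estimated correlation). Erythrocyte genes were higher in 6 of 6 (adjusted p = 4.29e-13, and adjusted p = 0.0138 with an estimated correlation), with Alas2, which starts haem synthesis in red cells (chromosome X, 150547375 to 150570638), at 8.56 ± 8.81 against 1.95 ± 1.79 CPM (SD; log2 fold change 1.93 ± 0.263, adjusted p = 1.22e-07). These 4 lists were those of 18 called that kept the call with an estimated correlation. Muscle genes were lower in 16 of 16 members, with a call lost at adjusted p = 0.243 with an estimated correlation. The models were split: the list was higher in 2250, 4T1, 9263, MMTV-PyMT and p53RB-626 (0.71 to 1.98). It was lower in the other models, down to -5.83 in KPB1-B. Type I interferon genes were lower in 9 of 28 members (17 adjusted over the list alone; adjusted p = 7.59e-06, and adjusted p = 0.538 with an estimated correlation). Gzmb, Pdcd1, Ctla4, Cd8a and Cd274 passed no test. Egfr was lower (-0.33 ± 0.0704) and Mki67 higher by 0.24 ± 0.0891. With 1 difference per model as the unit limma called 0 genes (2530 at unadjusted p under 0.05; lowest adjusted p 0.2), while DESeq2 over tumours called 3976. Counts were 635 without the tumours highest in muscle, 1977 with muscle and adipocyte levels as covariates, 296 without a term for the model and 1019 to 2446 without 1 replicate of every group. In the 5 near models 372 genes were called and in far models 4410, with p53 list changes of -0.35 ± 0.11 and -0.54 ± 0.18 (SE) and erythrocyte changes of 1.32 ± 0.38 and 2.61 ± 0.43.

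**Figure D1:**
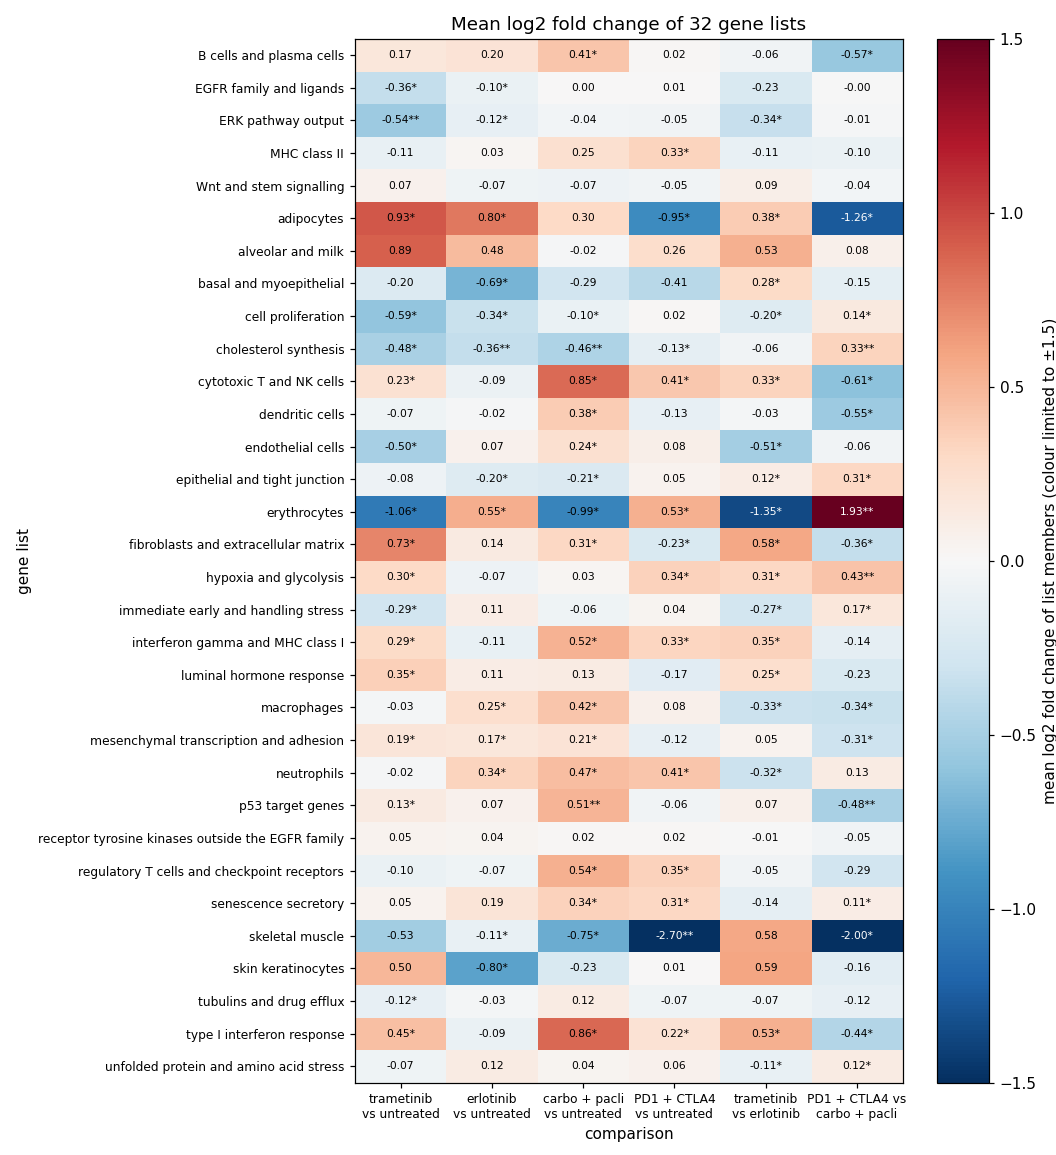
Mean log2 fold change over the measured members of each of the 32 lists (rows) in the 6 comparisons (columns), coloured from blue (lower) to red (higher), with 1 asterisk at camera adjusted p under 0.05 and a pair where this held with an estimated correlation. Skeletal muscle reaches the deepest blue in both columns of the antibodies, and the cholesterol list is blue against untreated tumours in every column where it is marked.

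In no called list of these comparisons did the median or mean fold change differ in sign from the test. Further lists called with trametinib were hypoxia and glycolysis, with 8 of 18 members higher (adjusted p = 0.474 with an estimated correlation), and luminal hormone response, with 7 of 14 higher (0.187). So were p53 targets, with 8 higher and 2 lower of 24 (0.187), and tubulins and drug efflux, with 9 lower and 3 higher of 15 (0.187). EGFR family and ligands had 5 lower and 1 higher of 13 (0.13), and immediate early and handling stress 7 lower and 3 higher of 16 (0.474). Erlotinib lowered 4 of 12 basal and myoepithelial genes (0.706), and the list of skin keratinocytes was called with none of its 5 members past the test alone (0.611). Trametinib lay below erlotinib in 5 genes of unfolded protein and amino acid stress (0.354). Chemotherapy raised 7 of 16 genes of B cells and plasma cells (0.559), 5 of 14 of dendritic cells (0.613), and 10 of 20 of the senescence secretory list, with 1 lower (0.424). The antibodies moved the MHC class II list upwards with none of its 8 members past the test alone (0.634). Adipocyte genes rose in 8 of 14 members with trametinib (0.579) and in 2 of 13 with erlotinib (0.706). Erythrocyte genes fell in 5 of 5 with trametinib (0.408) and in 3 of 6 with chemotherapy (0.424). Mesenchymal genes rose in 5 of 13 with trametinib (0.541) and cytotoxic genes in 5 of 22, with 1 lower (0.474). Chemotherapy also raised 20 of 25 genes of interferon gamma and MHC class I (0.424), 10 of 19 endothelial genes (0.559) and 6 of 23 matrix genes (0.6), and lowered 5 of 23 epithelial genes (0.689). The antibodies raised 8 of 20 genes of the senescence secretory list, with 1 lower, and 4 of 17 of neutrophils, and lowered 4 of 19 of cholesterol synthesis (each 0.618). Trametinib lay above erlotinib in 10 of 18 hypoxia genes (0.365) and below it in 5 of 5 erythrocyte genes (0.052) and 13 of 35 proliferation genes (0.399). The antibodies lay below chemotherapy in 9 of 22 cytotoxic genes (0.585), 8 of 13 mesenchymal genes (0.156) and 9 of 12 adipocyte genes (0.486), and above it in 11 of 23 epithelial genes (0.486). The alveolar and milk list was called in none of the comparisons with untreated tumours. Lists not called that did so include the basal and myoepithelial list with trametinib, with a test upwards and a median of -0.38. Receptor tyrosine kinases outside the EGFR family (adjusted p = 0.757 with trametinib), Wnt and stem signalling (0.538), and the senescence secretory list (0.69) were not called there.

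The design also asks whether the models respond alike. The interaction test answers this only together with library number, since the distance between arms also differed by model. By it the change with trametinib differed between models in 14261 of 18106 genes (98 tumours, 15 models), and to erlotinib in 13675 of 18017. For carboplatin plus paclitaxel 12555 of 18484 genes differed, and for the antibodies 11119 of 18435 (73 tumours, 11 models). Without 1 replicate of every group these counts were 8236 to 10754, 6887 to 12040, 7394 to 9145 and 4233 to 5848. The ERK pathway output list was lower with trametinib in 15 of 15 models, from -0.87 in KPB1-A to -0.21 in p53RB-624. With erlotinib it ranged from -1.39 in MMTV-Neu to 0.57 in KPB25L-UV, models whose skeletal muscle list rose by 4.47 and 2.62, exceeded only by 5.31 in KPB1-B. Within single models a median of 1084 genes was called with trametinib (57 in KPB25L to 8682 in MMTV-PyMT) and 274 with erlotinib (6 in T11-APOBEC to 11222 in MMTV-Neu). The MMTV-Neu tumours given erlotinib differed strongly from each other. Their pairs had a chi-square per degree of freedom of 993 to 3172 between counts, against a median of 139.7 over all pairs within groups. Chemotherapy gave a median of 2828 (8 in p53RB-624 to 9838 in C3-TAG), and the antibodies 930 (111 in 2153 to 4398 in T12). Without 1 replicate the medians were 369 to 584, 79 to 340, 355 to 1861 and 160 to 440. Proliferation changed with chemotherapy from -0.78 in KPB1-B to 0.83 in MMTV-Neu, and the cytotoxic list with the antibodies from -0.66 in C3-TAG to 2.02 in KPB1-A. Over the 56 pairs of model and treatment, calls rose with the distance in library number between the arms (Spearman's rho = 0.589, permutation p = 1e-05, the smallest they can give; Pearson's r with log10 calls = 0.498, permutation p = 7e-05). The pairs came from 15 models, and pairs of 1 model share untreated tumours. Both permutations ignored this, so their p-values may be too small. Without the 2 pairs farthest from the median distance r was 0.527. Within treatments, where each model enters once, rho was 0.712 with trametinib, 0.670 with erlotinib, 0.559 with chemotherapy and 0.373 with the antibodies. The plot of calls per model shows their spread.

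**Figure D2:**
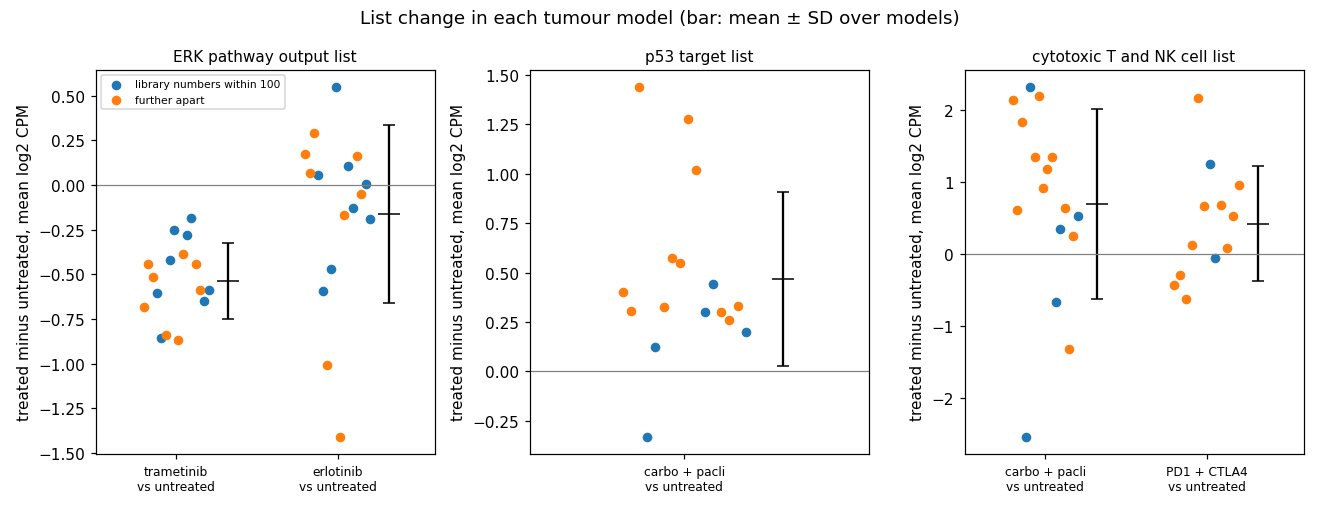
Change of the mean log2 CPM of 3 lists, treated minus untreated, with 1 point per model, blue where mean library numbers lay within 100 and orange where further apart, and bars for the mean ± SD over models. The ERK list lies below 0 in all 16 models with trametinib and on both sides of 0 with erlotinib.

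**Figure D3:**
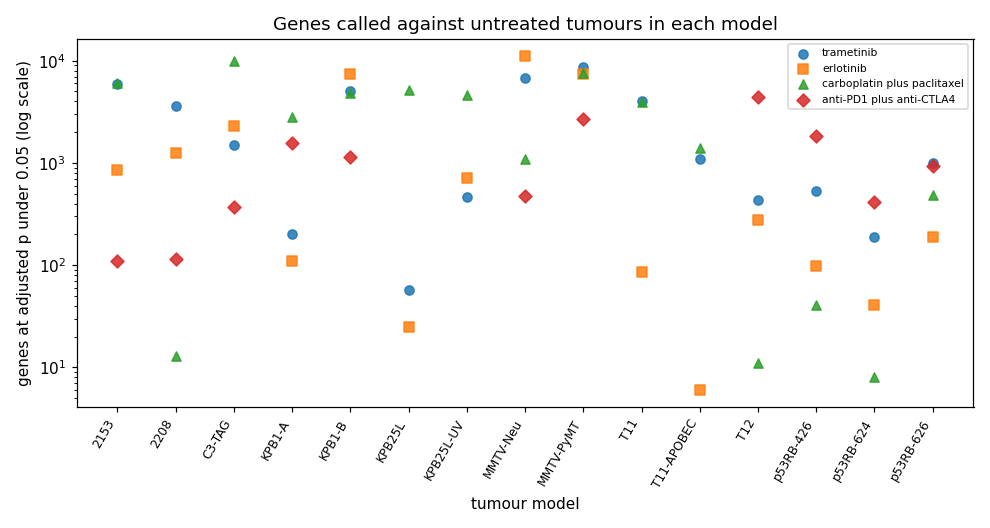
Genes at adjusted p under 0.05 against untreated tumours (log scale) in each tumour model, with 1 symbol per treatment. Calls run from 6 for T11-APOBEC with erlotinib to 11222 for MMTV-Neu with erlotinib.

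A pair of derivative models was compared untreated with the model whose name they extend, to ask what APOBEC mutagenesis or ultraviolet exposure, as their names read, left in expression. Interferon gamma, antigen presentation and cytotoxic lists were higher in T11-APOBEC and cholesterol synthesis lower, but few single genes passed. In KPB25L-UV the differences of keratin and haemoglobin genes rested on single tumours. T11-APOBEC (n = 3) differed from T11 (n = 4) in 135 of 22779 genes, 27 higher and 108 lower. Without 1 of these tumours the count ran from 21 to 187. Krt18, a keratin of simple epithelia (chromosome 15, 102028180 to 102032027), was lower, at 4.48 ± 0.878 against 28.1 ± 5.59 CPM (SD; log2 fold change -2.65 ± 0.347, adjusted p = 2.67e-06), and Sqle, a cholesterol enzyme, was lower as well (-1.20 ± 0.201). Cholesterol synthesis was lower in 3 of 19 members (16 adjusted over the list alone; adjusted p = 6.46e-15, and adjusted p = 0.15 with an estimated correlation). Cd274 was higher by 1.19 ± 0.3 (adjusted p = 0.0409), and Gbp6, an interferon-induced GTPase, by 2.04 ± 0.499. In the interferon gamma and MHC class I list 1 of 25 members was higher (13 adjusted over the list alone; adjusted p = 1.58e-16, and adjusted p = 0.15 with an estimated correlation), and in the MHC class II list 8 of 8 were higher adjusted over the list alone and none over all genes (edgeR; adjusted p = 1.06e-10, and adjusted p = 0.15 with an estimated correlation). Of 24 cytotoxic genes 12 were higher adjusted over the list alone and none over all genes (edgeR; adjusted p = 1.32e-14, and adjusted p = 0.202 with an estimated correlation). Chance could not be excluded: of 35 ways to divide these 7 tumours, another gave 139 calls. Fitted on the 2 groups alone, edgeR called 6 genes and DESeq2 767. KPB25L-UV (n = 3) differed from KPB25L (n = 3) in 267 genes, 188 higher and 79 lower, and in 121 to 371 without 1 of these tumours. Krt10, a keratin of skin, had 242 ± 415 CPM against 1.89 ± 0.0653, and its high mean came from KPB25L-UV replicate 3. Haemoglobin Hbb-bs, at 39.2 ± 11.1 against 501 ± 817 CPM, was lower through KPB25L replicate 1: without that tumour its log2 fold change was 0.41. Acta2, the actin of smooth muscle, was lower at 106 ± 60.9 against 391 ± 152 CPM (adjusted p = 0.0205). The 10 ways to divide these 6 tumours are too few for a share under 0.05; one other gave 724 calls, which points to a structure among these tumours. On the 2 groups alone edgeR called 0 of 15643 genes (991 at unadjusted p under 0.05) and DESeq2 124.

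The last question was whether the expression of untreated tumours goes with the gain in survival, over 32 relations of 8 list levels with 4 treatments. A pair of relations passed for Pearson's r and 0 for Spearman's rho (6 and 3 at unadjusted permutation p under 0.05). Models with low levels of interferon gamma and MHC class I genes gained more from carboplatin plus paclitaxel (16 models; r = -0.74, permutation p = 0.00089, adjusted p = 0.0285; rho = -0.68, adjusted p = 0.0762). So did those low in cytotoxic T and NK cell genes (r = -0.71, adjusted p = 0.0344; rho = -0.68, adjusted p = 0.0762; permutation tests). Epithelial, macrophage and type I interferon levels went with the same ratio without passing (r = 0.60, -0.61 and -0.61; permutation p = 0.0136, 0.0119 and 0.0129; each adjusted p = 0.0874). Without the 2 models farthest from the median level r was -0.61 for the interferon gamma list and -0.57 for the cytotoxic. It was 0.61 for the epithelial, -0.34 for the macrophage and -0.32 for the type I interferon list. The removed models were E0771 and KPB1-B for each interferon list, and E0771 and KPB1-A for the cytotoxic list. For the macrophage list they were KPB1-A and KPB1-B. The interferon gamma and cytotoxic relations were thus not tested with KPB1-A and KPB1-B left out together. KPB1-A and KPB1-B had the lowest levels and the largest ratios. Changes of a list with its treatment, over 4 relations, passed no test (lowest adjusted permutation p 0.175).

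**Figure D4:**
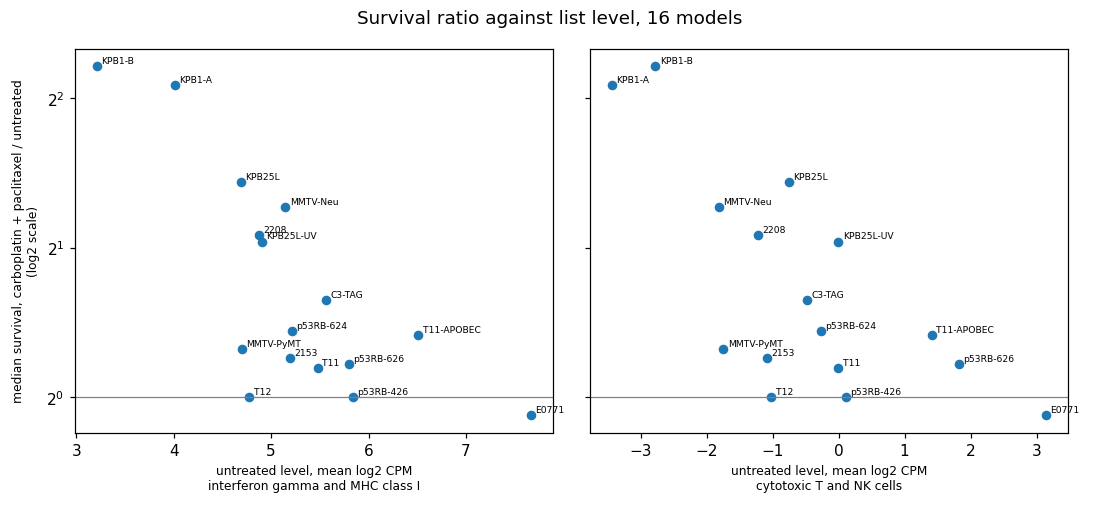
Ratio of median survival with carboplatin plus paclitaxel to that untreated (log2 scale) against the mean log2 CPM of the interferon gamma and MHC class I list (left) and the cytotoxic T and NK cell list (right) in untreated tumours, with 1 point per model. KPB1-A and KPB1-B lie at the top left, with ratios of 4.25 and 4.64.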

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

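Among the tests in this part, those of the spread of muscle genes within groups, of muscle in the near models, with muscle and adipocyte covariates, without the tumours highest in muscle and of the cholesterol and proliferation lists against library number were chosen only after the result was seen.

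In 5 untreated groups of 4 to 10 tumours, 6 of 100 values lay far from the rest of their group. Chance does so for about 1 in 20 values, so this number is close to what chance gives. All are log2 CPM. Esr1 in C3-TAG replicate 1 was at 2.65, against 3.60 to 3.74 in the other tumours of that model. In KPB1-B the cytotoxic T and NK cell list of replicate 3 was at -1.29, against -3.81 to -2.93. S100a8 in that tumour was at 0.19, against 1.43 to 2.12, and Brca1 in replicate 2 at 3.29, against 4.48 to 5.06. Krt14 in p53RB-626 replicate 2 was at 5.81, against -1.01 to 0.98. The epithelial and tight junction list of K14-TRT replicate 9 was at 0.37, above all other tumours of that model, which lay below 0.

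Changes against untreated tumours differed between models by a test of the difference itself, which does not separate the drugs from distances in library number that also differ by model. By the interaction test the trametinib response differed in 14261 genes, the erlotinib response in 13675, that to carboplatin plus paclitaxel in 12555 and that to anti-PD1 plus anti-CTLA4 in 11119. With residuals of the fit without interaction permuted, the ERK pathway output change differed between models with trametinib (permutation p = 0.043) and with erlotinib (permutation p = 1e-04, the smallest they can give). The proliferation change with carboplatin plus paclitaxel differed as well (permutation p = 1e-04, the smallest they can give), and so did the cytotoxic T and NK cell change with the antibodies (permutation p = 0.0408).

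The fall of skeletal muscle genes with anti-PD1 plus anti-CTLA4 was weighed first. Muscle carried along at dissection may contribute: the list spread between tumours of 1 group 5.60 times as much as the median of the other lists (SD 1.41 against 0.252, over 97 groups). That spread alone does not show a difference between the arms. The list was lower in every model, and whether dissection left the arms with a different muscle content was not tested. Against the same untreated tumours it also fell in many models with erlotinib and chemotherapy, as in p53RB-624 and 2208. In others it rose, as in KPB1-B with both. Whether untreated tumours rich in muscle, shared by these comparisons, add to the fall was not tested. Part of the calls of this comparison may follow that content, but the tests differ: without the tumours highest in muscle 2151 genes were called, 1533 of them among the 2495, while with muscle and adipocyte levels as covariates 45.1% of the other called genes kept their call (1114 of 2471), among them 7 of 7 cytotoxic and 8 of 8 interferon gamma genes but 2 of 13 hypoxia genes. Collection or preparation of the arms at different times stays open, because only 2 models had near library numbers, with a mean change of -1.69 ± 0.866 (SE) against -2.78 ± 0.472 in the others. A loss of muscle through the treatment itself was not tested.

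The number of genes called per model was weighed next. A difference between batches may add to it, since calls rose with the distance in library number between the arms (rho = 0.589 over 56 pairs of model and treatment). That distance is between means. For some treatments of KPB1-B, T11 and p53RB-626 part of the untreated tumours lay beside the treated ones despite a large distance. Sequencing depth (rho = 0.262, permutation p = 0.0487) and the absolute change of the skeletal muscle list (rho = 0.0214, permutation p = 0.879) were neither shown nor excluded. Fat content was not tested. Within treatments the rho of depth was 0.143 with trametinib, 0.232 with erlotinib, 0.246 with chemotherapy and 0.655 with the antibodies. Models that truly respond more remain an explanation that these data leave untested, because library number and model go together.

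Cholesterol and proliferation genes were lower with several treatments, and the third pattern weighed was whether shared untreated tumours explain it. For trametinib and erlotinib, each drug was taken from separate models, so that no untreated tumour was shared. Both lists were then below 0 in both sets in 99% of 100 splits of the models. The falls thus did not need a shared tumour, but the splits cannot weigh the untreated arm as a cause. The mean changes over all models were below 0 to begin with, and an offset common to the untreated tumours would stay in every split. A difference between batches could not be told apart from the drugs for the size of the fall: in models with near library numbers the smaller median fall with trametinib was -0.110, for cholesterol (SE 0.134, 7 of 8 models below 0), and that of proliferation was -0.247 (SE 0.0878, 7 of 8). With erlotinib the near mean of proliferation was -0.02 ± 0.046 (SE), while with chemotherapy that of cholesterol was -0.44 ± 0.12 in near and -0.44 ± 0.096 in far models, so the treatments differ here. An effect of slower growth on both lists was not tested.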

How the results depend on the processing

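Of the tests behind the alternatives below, depth, muscle and adipocyte covariates, leaving out the tumours highest in muscle, and the near and far sets of the antibodies against chemotherapy were chosen only after the result was seen.

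Counts moved by less than 1.5 times with DESeq2, RLE factors and no low-count filter in the 6 treatment comparisons. With limma on the authors' normalized table totals did so except for erlotinib, but directions moved: erlotinib had 2768 genes (306 higher, 2462 lower; 849 and 942 otherwise), chemotherapy 5128 and 736 (2852 and 2057 otherwise), the antibodies 2037 and 586 (1353 and 1142), trametinib against erlotinib 3024 and 1506 (2231 and 2214). That scaling shifts log2 fold changes by -0.06 with erlotinib and 0.10 with chemotherapy; the test differed too, and the causes were not separated. Without a model term trametinib had 1357 genes, erlotinib 172, chemotherapy 782, the antibodies 279, trametinib against erlotinib 239 and the antibodies against chemotherapy 296. With 1 difference per model as the unit these were 1559, 0, 0, 0, 394 and 0. Without the tumours highest in muscle they were 4370, 461, 2139, 2151, 2579 and 635. Near models alone gave 4.7e+03 (rounded) for trametinib, 190 for erlotinib, 0 for chemotherapy, 150 for the antibodies and 372 for the antibodies against chemotherapy, and far models 4.5e+03 (rounded) for the antibodies. Marked untreated tumours gave 2225 for chemotherapy and 1367 for the antibodies, and depth as a covariate 3071 and 717. Muscle and adipocyte covariates gave 1977 for the antibodies against chemotherapy.

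Leaving out 1 replicate of every group gave 5022 to 5897 genes for trametinib, 252 to 864 for erlotinib, 2394 to 3628 for chemotherapy, 524 to 1006 for the antibodies, 1894 to 3112 for trametinib against erlotinib and 1019 to 2446 for the antibodies against chemotherapy. No paired analysis was possible because replicate numbers only name the order of the tumours. Leaving out 1 model gave 1152 without KPB1-B and 1111 without MMTV-Neu for erlotinib. For the antibodies it gave 3990 without MMTV-PyMT, 1199 without p53RB-426, 1577 without p53RB-626 and 1412 without T12. The interactions ran from 8236 to 10754 (trametinib), 6887 to 12040 (erlotinib), 7394 to 9145 (chemotherapy) and 4233 to 5848 (antibodies) without 1 replicate.

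Median genes per model were 3248, 574, 1872 and 1547 for trametinib, erlotinib, chemotherapy and the antibodies with each model and all its arms fitted alone, and without 1 replicate 369 to 584, 79 to 340, 355 to 1861 and 160 to 440. Untreated models had 22211 to 22317. With no filter the variance shares were 41.7% model, 19.1% interaction and 36.6% within groups. Lists called with an estimated correlation in place of the preset one numbered 1 with trametinib, 1 with erlotinib, 2 with chemotherapy, 1 with the antibodies, 0 for trametinib against erlotinib (17 otherwise, camera), 4 for the antibodies against chemotherapy and 0 for each derivative (12 otherwise, camera). Survival with the antibodies in days had an exact permutation p of 0.0605.

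T11-APOBEC against T11 had 6 genes in edgeR on the 2 groups alone, 767 in DESeq2, 407 with the normalized table and 21 to 187 without 1 replicate (65 without T11 replicate 1; 30, 21 and 60 without T11-APOBEC replicates 1, 2 and 3). KPB25L-UV against KPB25L had 0 in edgeR alone (991 at unadjusted p under 0.05), 124 in DESeq2 and 121 to 371 without 1 replicate (165 and 121 without KPB25L replicates 1 and 2, 168 without KPB25L-UV replicate 3).

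Over 5133 values of named genes under alternatives, 4409 kept their side of the threshold (90 of these, never called, had another sign), 643 lost the call, 61 gained one and 20 that had been called changed sign or, for Dsc1, went to 0. All of the last are log2 fold changes. In near models Mki67 with erlotinib was at 0.0307; with chemotherapy Ctla4 was at -0.47, Cd8a at -0.10, mt-Atp8 at 0.34 and mt-Nd2 at 0.0714; and with the antibodies Egfr was at 0.16, Gzmg at -1.24, Gzmf at -1.13 and Car3 at 0.39. Muscle and adipocyte covariates put Pvalb at 0.00609, Acta1 at 0.10 and Car3 at 0.0398 with the antibodies, and Pvalb at 0.22 against chemotherapy, by construction. Without a model term Gzmb was at -0.19 with trametinib against erlotinib. For KPB25L-UV, values without 1 replicate ran from -4.71 (without KPB25L-UV replicate 2) to 1.57 for Ppp1r3c. Hba-a2 ran from -4.53 to 0.0637, Hbb-bs from -4.24 to 0.41 and Hba-a1 from -4.14 to 0.48, lowest without KPB25L replicate 3, and all of these were positive only without KPB25L replicate 1. Lgals7 ran from -0.57 without KPB25L-UV replicate 3 to 9.94, and Dsc1 was at 0.00 without that tumour.

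Depth limits rare transcripts most in the libraries of 12.1 M counts. The cause of these differences was not tested beyond the smaller number of tumours in most of them.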

Other observations

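None of the tests in this part was chosen after its result was seen.

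Tumours were divided in other ways to see whether chance gives as many calls, with up to 100 splits per result, the real one included. In the following 15 results only the real split gave its number of calls, 1 of 100 splits (1 of 60 within models). For the treatment comparisons and the medians within models chance is thus an unlikely cause. Shuffling arms within models also removes any treatment effect that models share, so it cannot weigh chance for responses differing between models. Untreated models differed so widely that shuffled labels could hardly give as many calls, so that split adds little. Trametinib had 7215 calls (highest other 49), erlotinib 1791 (761), carboplatin plus paclitaxel 4909 (4811), anti-PD1 plus anti-CTLA4 2495 (92), trametinib against erlotinib 4445 (249) and the antibodies against chemotherapy 3942 (1045). Responses differing between models had 14261 (5522) for trametinib, 13675 (6499) for erlotinib, 12555 (8123) for chemotherapy and 11119 (1760) for the antibodies. Medians within single models, each fitted on the 2 compared arms only, were 1369 (53), 277 (12), 2002 (73) and 1259 (229) in that order, and untreated models had 22520 (6602). For T11-APOBEC chance could not be excluded, with 2 of 35 splits at 135 calls or more (highest other 139). For KPB25L-UV the 10 splits were too few, with 267 calls and a highest other of 724.

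The p53 target response to carboplatin plus paclitaxel might depend on how much Trp53 mRNA a model has. Over 16 models rho was 0.0265 (permutation p = 0.926) and Pearson's r was 0.175 (permutation p = 0.521; 0.0477 without the 2 farthest models), which neither shows nor excludes such a relation; Trp53 mRNA does not tell mutant from wild-type protein.

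The fall of ERK pathway output with trametinib might come from fewer cycling cells. With the proliferation list level as a covariate the list kept 83.8% of its change (-0.55 ± 0.0424 before and -0.46 ± 0.0547 after, SE), which argues against that as the whole cause.

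Whether the KPB25L-UV chemotherapy tumours whose library names begin with KPB25L are KPB25L tumours could not be told apart. The test needed genes that separate these models with trametinib and with erlotinib, and edgeR found 0 in both (2 called and 1491 at unadjusted p under 0.05 with trametinib, none and 869 with erlotinib, of 18104 genes; no other tool was run).

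K14-TRT had only untreated tumours, and KPB25L-APOBEC was a single untreated tumour; values of the latter enter no comparison. Among 355 pairs of tumours of the same group no pair had identical counts, and the lowest chi-square per degree of freedom was 7.49 (median 139.7), so tumours of a group differed beyond counting error. The highest was 3172, between MMTV-Neu tumours given erlotinib.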
